A study of Mus musculus with 4 samples.

How the data were processed

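Small RNA libraries were prepared from MLE12 cells, a transformed mouse lung epithelial line. Per the labels, the cells were either left untreated or given 10% cigarette smoke extract (CSE) for 10 h, with 2 biological replicates of each, all at passage 3. The extract was the smoke of 1 cigarette drawn through 5 ml of medium and passed through a 0.22 um filter. Per the labels' protocols, total RNA was treated with DNase and phosphatase, labelled at its 5' ends with radioactive phosphate and run on a denaturing gel, and RNA of 15 to 100 nt was taken. A 3' adaptor that opens with 4 random bases was ligated, and barcoded libraries were pooled and read from both ends for 75 bp on a NextSeq.

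The deposited values are read counts: each row of the authors' tables gives a distinct aligned fragment with its count, start, end, length and sequence, in 1 table per library. The table names state that reads were aligned with BLASTN to positions 16116 to 16210 of the mouse mitochondrial genome. The BLASTN version and settings, read trimming, the joining of read pairs and any collapsing of copies are not given in the sources used here. Counts were not normalized and no total per library accompanies them, so the number of reads listed is not a sequencing depth. More reads listed for this region in 1 library can reflect more RNA of the region or a larger library.

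Groups were taken from the name of each table, which marks it as a smoke or a control library. The tables of treated cells are numbered 3 and 4 and those of untreated cells 1 and 2, while the labels number both groups 1 and 2. No table was therefore tied to a single labelled replicate. The libraries are called CSE 3, CSE 4, untreated 1 and untreated 2 after the tables.

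The tables number positions up to 190, which is 2 joined copies of the 95 nt region. All 65 positions of the second copy that reads cover hold the same base as the first copy. Reads wholly in the second copy, 1 to 5 per library, were moved to the first, and the 23 reads across the join were kept. Positions are those of the tables, from 1 at the first base of the listed sequence. Whether this numbering runs along or against the genome coordinates was not settled, because no mitochondrial sequence was used here. The same base order was found in every row: 0 bases conflicted between fragments and 0 rows matched the opposite strand. Listed reads were 28 to 70 nt long, although a second table of counts per length opens at 1 nt. That table matched the row sums at every length. Reads that stop at position 95 or reach 70 nt may continue beyond what is listed, so their 3' ends were not observed. They made up 25.7% ± 2.94 (SD, n = 2) of CSE and 20.2% ± 0.0788 (n = 2) of untreated reads.

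For each library the read number, median length, shares of 3 length classes, share at the most used 5' and 3' ends, coverage at 3 positions and number of distinct fragments were computed. Distinct fragments were averaged over 1000 seeded draws of 984 reads, the smallest library. Groups were compared with the two-sided exact permutation test of the library values, which with 2 against 2 cannot give a p below 0.333. Pooled reads were compared with Fisher's exact test, two-sided. Fisher's test compares the reads of these libraries and not the conditions, and its p-values are too small because replicates differed by more than sampling noise. A chi-square test of fragment counts gave p = 9.087e-15 between the CSE libraries and 0.00637 between the untreated ones. The tests on pooled reads and the scan described next nonetheless treat each pair as 1 library. Means with SD, the permutation test and the count models keep the replicates apart. Intervals per library are 95% Wilson intervals for shares and exact Poisson intervals for counts. Both cover counting error only, since copies of 1 molecule were not separated.

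Each 5' end, 3' end and fragment with at least 10 reads over the 4 libraries was also scanned with Fisher's exact test on pooled reads and Benjamini-Hochberg adjustment per kind. A feature was called where the adjusted p was under 0.05 and both CSE libraries lay on the same side of both untreated ones. Chance gives the latter for 33.3% of unchanged features if all 4 libraries have equal counting error. The untreated libraries list fewer reads, so their shares vary more, and chance can give a higher share. Named features are the 5 most abundant 5' ends, 5 most abundant 3' ends and 10 most abundant fragments by mean share. Of the called features of each kind, the 5 with the largest fold up and the 5 with the largest fold down were added. These tests, the named features and most alternatives were set before the data were examined. The contrast of 53 to 54 nt reads and the scan of single read lengths were chosen after the length profiles were seen.

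Count models that use the spread between replicates were added after the data were seen: edgeR's quasi-likelihood test with the reads listed as library size or with TMM factors, and DESeq2 with its size factors. Other alternatives counted each distinct fragment once, left out a library at a time, moved the read minimum or the length classes, pooled ends within 2 nt, left out reads without an observed 3' end, or left out 53 to 54 nt reads. A further alternative left out the reads that lie in or reach into the second copy. The planned shares per strand and of mismatched reads could not be compared, as every row held 1 strand and no mismatch.

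The scan and the models were tested on simulated data with the real read numbers and 2- or 4-fold changes. With the most abundant feature unchanged, the scan called 4 of 4 3' ends changed 4-fold, 2 of 4 changed 2-fold and 4 of 41 that did not change. In a simulation run before that one, the most abundant 3' end was itself among the 8 changed, raised 4-fold, and the scan called 20 of the 41 unchanged 3' ends. There edgeR with the reads listed as library size called 11 of them, edgeR with TMM factors 0 and DESeq2 0. A change at a dominant end shifts the shares of all others, and the simulation with that end unchanged was added after this outcome was seen. For 5' ends, with the most abundant one unchanged, the scan called 3 of 45 unchanged ends. For fragments in that simulation, it called 6 of 25 changed 4-fold, 0 of 22 changed 2-fold and 0 of 284 unchanged. The simulated spread between replicates was a single fixed value for all kinds, not fitted to these libraries. False calls under the real spread were therefore not measured.

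Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Genes were taken from GENCODE release M21, whose positions apply if the tables use the mitochondrial sequence of GRCm38.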

Results

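Small RNA reads from a segment of 95 nt of the mouse mitochondrial genome (chromosome MT, at the coordinates given above) were compared between MLE12 lung epithelial cells given cigarette smoke extract (CSE) and untreated cells. The comparison asked how smoke changes small noncoding RNAs. There were 2 libraries per group. The segment lies in the noncoding control region, the part of the mitochondrial genome from which transcription of both strands starts. None of the 37 mitochondrial genes in GENCODE M21 overlaps it (0 genes). The nearest annotated gene before it is mt-Tp, the gene of the mitochondrial proline tRNA, at 15356 to 15422 on the minus strand, 693 nt away. Genes on the other side of the segment were not searched, so a closer gene is possible. The sequence of the segment as listed is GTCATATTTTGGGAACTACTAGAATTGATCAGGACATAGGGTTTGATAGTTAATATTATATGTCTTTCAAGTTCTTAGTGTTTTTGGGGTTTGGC. No GENCODE transcript held an exact match to its bases 31 to 60 (0 transcripts).

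More reads of the region were listed for the treated cells. The CSE libraries held 5090 ± 518 reads (SD, n = 2) and the untreated libraries 1206 ± 313 (n = 2), a ratio of 4.22 or a log2 difference of 2.10. CSE 3 held 4724 reads (95% Poisson interval 4590 to 4861) and CSE 4 held 5456 (5312 to 5603). Untreated 1 held 984 (923 to 1047) and untreated 2 held 1427 (1354 to 1503). The lower CSE library exceeded the higher untreated library 3.31-fold. The exact permutation test gave p = 0.333, the smallest this design allows. Without totals per library, the ratio was not corrected for sequencing depth.

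**Figure D1:**
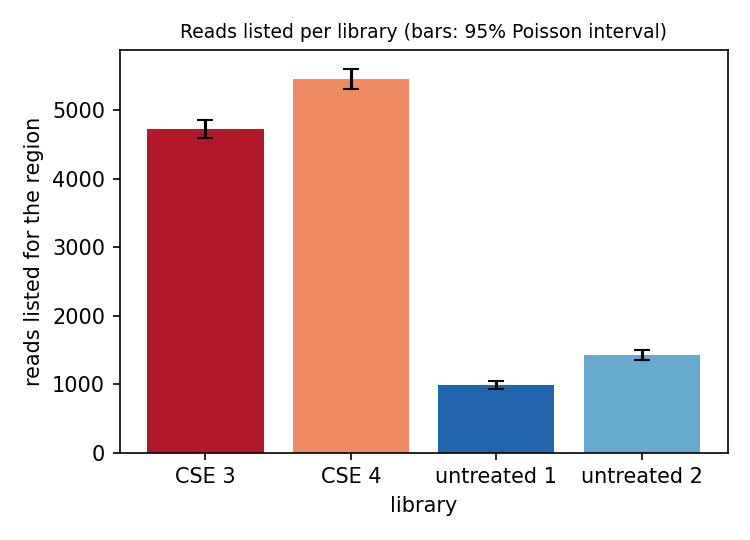
Reads listed for the mitochondrial region in each of the 4 libraries, with 95% Poisson intervals as error bars. The CSE libraries stand at 4724 and 5456 reads and the untreated libraries at 984 and 1427.

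Long reads formed a smaller share of the CSE libraries. Reads over 50 nt made up 30.9% ± 3.34 (n = 2) of CSE reads and 40.8% ± 2.85 of untreated reads. Reads of 31 to 50 nt made up 56.9% ± 1.74 and 48.9% ± 3.94. Neither class overlapped between the groups, with p = 3.267e-19 and p = 2.716e-11 in Fisher's exact test on pooled reads and p = 0.333 in the exact permutation test. The difference in reads of 31 to 50 nt moved from 7.96 to 5.17 percentage points without untreated 1, and to 4.79 without reads of 53 to 54 nt. With class limits at 25 and 40 nt, where no read falls in the shortest class, reads over 40 nt differed by -4.10 percentage points (Fisher's exact p = 3.309e-04). Reads of up to 30 nt took 12.2% ± 1.59 of CSE and 10.3% ± 1.09 of untreated reads. The libraries of this class overlapped, and its Fisher's exact p of 0.00365 became 0.258 without CSE 4 and 0.284 without untreated 2. Median length was 45 and 42 nt in CSE 3 and CSE 4 and 48 and 45 nt in untreated 1 and 2, which overlap (exact permutation p = 0.667).

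Part of that difference lay in a narrow length band. Without reads of 53 to 54 nt, the difference in reads over 50 nt was -6.04 instead of -9.85 percentage points. Reads of 53 to 54 nt formed 5.44% (Wilson interval 4.83 to 6.12) of CSE 3 and 5.55% (4.98 to 6.19) of CSE 4. In untreated 1 and 2 they formed 11.6% (9.73 to 13.7) and 11.8% (10.2 to 13.5). The untreated mean of 11.7% ± 0.133 (n = 2) was 2.12 times the CSE mean of 5.50% ± 0.0801 (Fisher's exact p = 1.685e-24). In the scan of 43 single lengths, 4 were lower in CSE, namely 53, 54, 56 and 61 nt, and 1 was higher, 43 nt. Length 54 nt fell from 6.62% ± 0.548 to 2.80% ± 0.243. With edgeR and the reads listed as library size, lengths 43, 53 and 54 nt passed the adjusted threshold (adjusted p = 0.0243 for 43 nt and 0.0115 for both others). With edgeR and TMM factors the 5 lengths of the scan passed. With DESeq2, 0 lengths passed, and 5 had an unadjusted p under 0.05. Leaving out 1 library at a time, the scan called 0 to 3 lengths higher and 2 to 3 lower, and 53 and 54 nt were called each time. The length band and this scan were chosen after the profiles were seen.

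**Figure D2:**
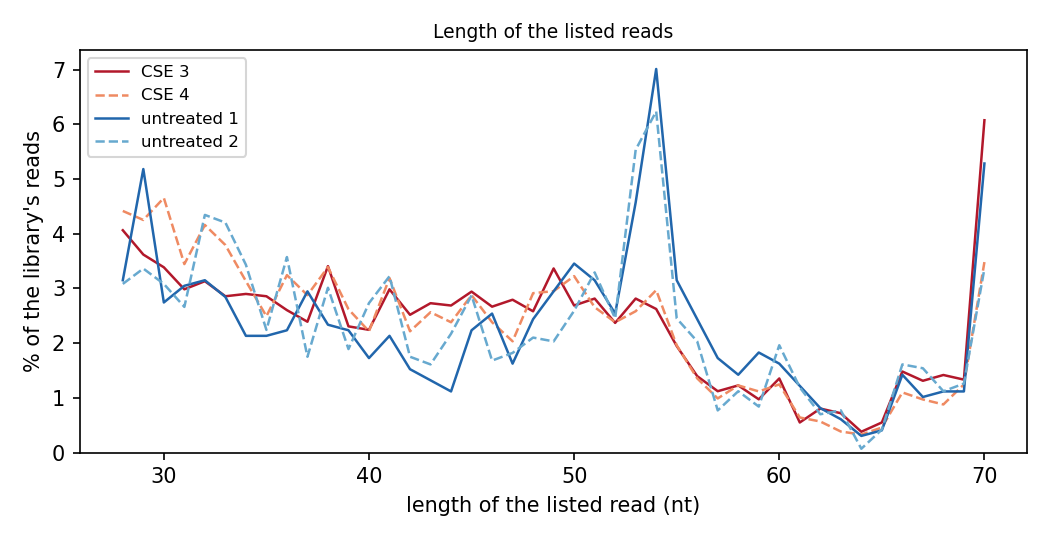
Share of each library's reads (percent) at each length (nt), 1 line per library. The untreated lines peak at 54 nt, at 7.01% and 6.24%, where the CSE lines stand at 2.62% and 2.97%.

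Reads began most often at position 22 in all 4 libraries. That 5' end held 25.1% ± 0.00091 (n = 2) of CSE reads and 24.6% ± 1.75 of untreated reads. The difference was within the spread between untreated replicates (Fisher's exact p = 0.433), and its interval on pooled reads ran from -1.13 to 2.69 percentage points. Position 22 corresponds to 16137 if the tables number along the genome and to 16189 if they number against it. The next most used 5' ends were 27, 55, 58 and 26. Position 27 held 4.46% ± 0.283 of CSE and 5.91% ± 0.458 of untreated reads and was called lower in CSE (Benjamini-Hochberg p = 0.0211 in Fisher's exact test). Positions 55, 58 and 26 held 4.37%, 3.31% and 3.66% of CSE and 3.81%, 3.54% and 3.08% of untreated reads, with overlapping libraries. Reads that start at position 22 had a median length of 56 and 51 nt in CSE 3 and CSE 4 and 57 and 55 nt in untreated 1 and 2.

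Of 53 tested 5' ends, 3 were called higher and 5 lower in CSE. Position 51 rose from 1.17% ± 0.0695 to 2.75% ± 0.752 (n = 2 each, 2.35-fold, adjusted Fisher's exact p = 1.027e-04), and positions 39 and 45 rose 2.44- and 2.05-fold. Positions 20, 35, 36, 30 and 27 were lower in CSE, with untreated over CSE ratios of 4.75, 1.97, 1.94, 1.75 and 1.33. Without reads of 53 to 54 nt, the difference at position 35 turned from -0.747 to 0.147 percentage points, and the scan called 1 end higher and 1 lower. Position 20 rested on 24 reads in total and on untreated 1, which held 9 of them, and its ratio was 1.77 without that library, with no call, and 7.72 without untreated 2, still called. Groups did not overlap at 45.3% of tested 5' ends, against 33.3% by chance if counting error were equal. With edgeR, 0 5' ends passed with either scaling (9 and 8 at an unadjusted p under 0.05), and DESeq2 called only positions 51 and 36. The scan called 0 higher and 1 lower without untreated 2, 1 higher without untreated 1 and 3 lower without CSE 3. Of the 8 called 5' ends, 0 were called without each library in turn.

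Listed reads stopped most often at position 95, the last base of the region, and more so in CSE. Such reads may continue beyond it, so this is a share of reads that reach the last base and not an observed 3' end. It was 20.9% ± 1.21 (n = 2) of CSE and 16.0% ± 1.31 of untreated reads, without overlap (Fisher's exact p = 1.130e-07, exact permutation p = 0.333). The adjusted p was 0.0482 in edgeR with the reads listed as library size, 0.156 with TMM factors and 0.0283 in DESeq2. The next most used 3' ends, 87, 91, 88 and 81, held 6.74%, 6.61%, 5.15% and 4.93% of CSE reads and 7.21%, 5.48%, 5.61% and 5.79% of untreated reads, and none of these 4 was called. At position 91 the 3' end was not observed for 470 of 794 reads, which have the longest listed length of 70 nt.

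Of 49 tested 3' ends, 4 were called higher and 6 lower in CSE. Position 75 fell from 5.36% ± 1.04 to 3.05% ± 0.357 (n = 2 each, adjusted Fisher's exact p = 1.642e-05), with adjusted p = 0.0482 in edgeR with the reads listed as library size and 0.0174 in DESeq2. Positions 61, 83, 86 and 82 were lower too, with untreated over CSE ratios of 3.02, 1.94, 1.84 and 1.83. The ratio at 61 was 2.01 without CSE 3 and 6.08 without CSE 4. Positions 71, 49 and 55 were 4.01, 3.06 and 2.11 times higher in CSE. Untreated 2 held 0 reads that end at 71 or 49, which allows a share of up to 0.210%. Without untreated 2 these ends were 2.00 and 1.53 times higher in CSE and were not called (adjusted Fisher's exact p = 0.613 and 0.632). The scan called 1 higher and 2 lower without untreated 2, and 8 higher without CSE 3. Of the 9 called 3' ends named here, 2 were called without each library in turn, 75 and the last base, 95, where the true end was not observed. Groups did not overlap at 42.9% of tested 3' ends, against 33.3% by chance if counting error were equal. With edgeR and TMM factors, 0 3' ends passed (7 at an unadjusted p under 0.05), and the other models called position 75 and the last base, 95, alone. In simulated data, where the most abundant 3' end rose 4-fold and 7 others changed, this scan called 20 of 41 unchanged 3' ends. With the most abundant 3' end unchanged it called 4 of 41. The real share at the last base rose 1.31-fold, which neither simulation matched, so neither gives the share of false calls here.

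**Figure D3:**
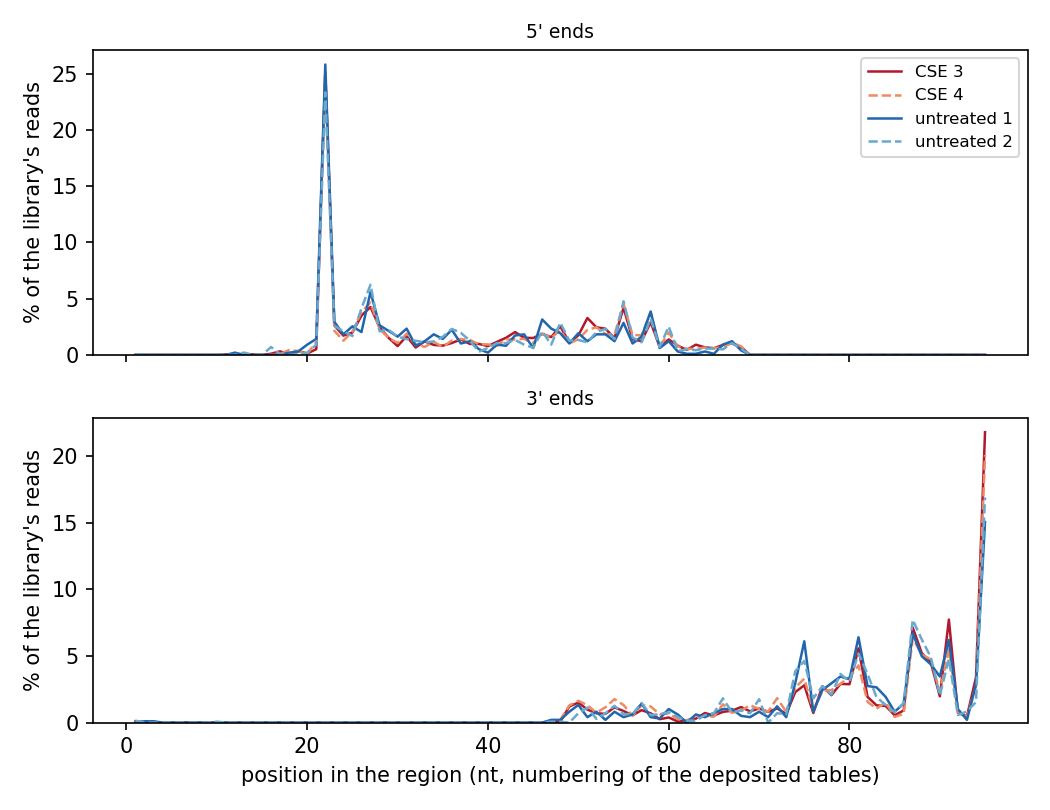
Share of each library's reads (percent) that start (upper panel) or end (lower panel) at each position of the region (nt), 1 line per library. All 4 libraries peak at 5' end 22, and at position 95, the last base listed, the CSE lines stand at 21.8% and 20.1% and the untreated lines at 15.0% and 16.9%.

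The most abundant fragment ran from position 22 to 91, with sequence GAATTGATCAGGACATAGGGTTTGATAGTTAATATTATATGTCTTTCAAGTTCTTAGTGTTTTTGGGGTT. It held 241 and 154 reads in CSE 3 and CSE 4 and 41 and 34 in untreated 1 and 2. Its shares of 3.96% ± 1.61 and 3.27% ± 1.26 (n = 2 each) overlapped (adjusted Fisher's exact p = 0.428). At 70 nt it has the longest listed length, so its 3' end was not observed. Of the other 9 most abundant fragments, 5 start at 22 as well, ending at 75, 87, 50, 81 and 88. The remaining 4, 55-95, 58-95, 46-95 and 67-95, reach the last base. None of these 10 fragments was called.

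Of 317 tested fragments, 2 were called higher and 8 lower in CSE. Fragment 47-95 held 0.695% ± 0.154 of CSE and 0.137% ± 0.0942 of untreated reads (n = 2 each, adjusted Fisher's exact p = 0.0125). With 3 untreated reads, its ratio on pooled reads was 5.53 with an exact interval of 1.81 to 27.4. The ratio of its mean shares was 5.09, and it was 9.92 without untreated 1, 3.42 without untreated 2 and 4.29 without CSE 3, with no call in any of these 3 cases (adjusted Fisher's exact p = 0.122, 0.617 and 0.0666). Fragment 22-49 held 49 and 62 reads in CSE 3 and CSE 4 and 7 and 0 in untreated 1 and 2, a 3.06-fold higher share. Without untreated 2 it was 1.53 times higher in CSE and was not called (Fisher's exact p = 0.328). Fragment 35-88, 54 nt long, held 1 and 5 reads in CSE 3 and CSE 4 and 5 and 12 in untreated 1 and 2, a share 12.0 times higher in untreated cells (adjusted Fisher's exact p = 5.834e-06, edgeR 0.00261, DESeq2 0.996). Fragments 41-94, 25-78 and 29-81 were lower in CSE, with untreated over CSE ratios of 9.09, 8.79 and 3.99 on 15, 17 and 25 reads. Without CSE 3 the ratios of 35-88, 41-94 and 25-78 were 7.36, 5.86 and 5.41, and without CSE 4 they were 31.9, 20.3 and 23.4. Without untreated 1 the ratio of 25-78 was 4.97. Fragment 27-60 was lower on 2 CSE and 8 untreated reads, with a pooled ratio of 16.9 and an exact interval of 3.37 to 163. Both CSE reads came from CSE 4. The ratio of its mean shares was 17.9, and without CSE 3 it was 8.94 and not called (adjusted Fisher's exact p = 0.0614). Without CSE 4 no CSE read was left, and without CSE 4, untreated 1 or untreated 2 it fell under the minimum of 10 reads. Of the 8 lower fragments, 5 were 53 to 54 nt long, a length held by 24 of all 317. That band was chosen from these same reads, where it was lower in CSE, so this is no independent result. Groups did not overlap for 45.1% of fragments, against 33.3% by chance if counting error were equal. edgeR with the reads listed as library size called 0 fragments higher and 1 lower, edgeR with TMM factors 2 and 1, and DESeq2 0 and 0 (8 at an unadjusted p under 0.05). Leaving out any 1 library, the scan called 1 to 4 higher and 1 to 5 lower, and 0 of the 7 called fragments named here were called each time.

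Coverage peaked at positions 67 and 66 in CSE 3 and CSE 4, at 86.7% and 82.6%, and at 60 and 64 in untreated 1 and 2, at 88.6% and 87.7%. At position 48, the middle of the region, 69.4% ± 0.472 (n = 2) of CSE and 74.1% ± 2.83 of untreated reads covered the base, without overlap (Fisher's exact p = 2.270e-05, exact permutation p = 0.333). The difference of -4.72 percentage points became -2.71 without untreated 1 (Fisher's exact p = 0.0365) and -6.72 without untreated 2. Among reads with both ends observed the difference was -1.63 percentage points and no longer passed (Fisher's exact p = 0.120). At position 80 the shares were 64.3% ± 4.54 and 63.6% ± 0.819, which overlap (Fisher's exact p = 0.654), and the difference was -2.58 percentage points without CSE 3 and 3.84 without CSE 4. Position 16, before the main 5' end, was covered by 0.174% ± 0.143 and 0.592% ± 0.550, which also overlap. Its Fisher's exact p of 1.304e-04 became 0.682 without untreated 2.

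**Figure D4:**
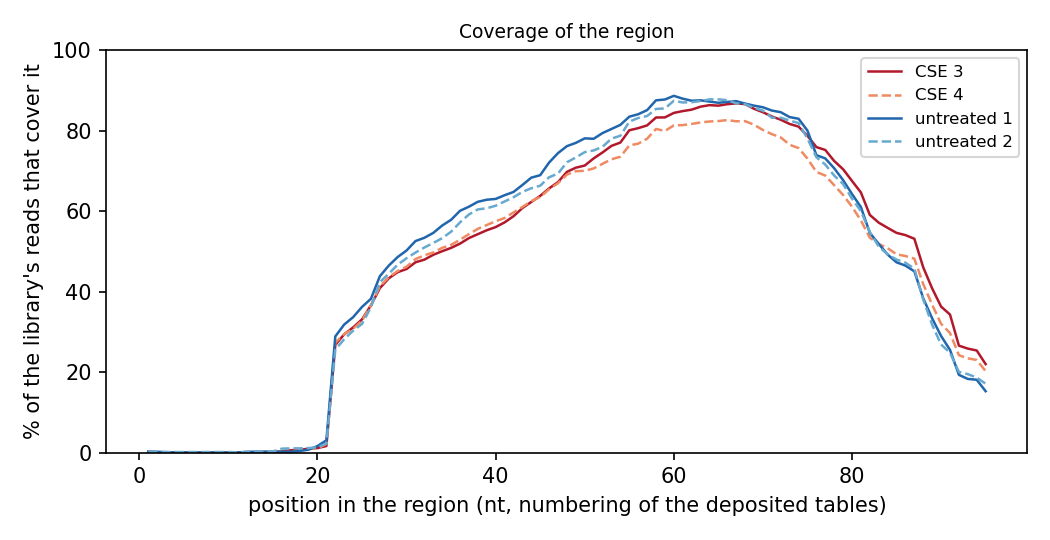
Share of each library's reads (percent) that cover each position of the region (nt), 1 line per library. At position 48 the CSE lines stand at 69.7% and 69.1% and the untreated lines at 76.1% and 72.1%.

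With equal numbers of listed reads drawn, the libraries held similar numbers of distinct fragments. In draws of 984 reads, CSE libraries held 416 ± 7.26 (n = 2) and untreated libraries 389 ± 10.6 distinct fragments, a ratio of 1.07 without overlap (exact permutation p = 0.333). Without thinning the numbers were 787 and 834 against 382 and 466, a ratio of 1.91.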

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

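The count models, the scan of lengths and the settings on observed ends, on the second copy and on 53 to 54 nt reads were chosen after the data were seen. The higher read number, the shorter lengths (31 to 50 and over 50 nt), the lower share of 53 to 54 nt reads and the higher number of distinct fragments kept their direction under every setting run for them, as did the median length difference. Their size did not always hold: reads of 31 to 50 nt differed by 7.96 percentage points, and by 4.79 without 53 to 54 nt reads and 5.17 to 10.7 without 1 library. Reads over 50 nt differed by -9.85, and by -6.04 and -12.2 to -7.49 under these same settings. With class limits at 25 and 40 nt, no read falls in the shortest class. Reads up to 40 nt and over 40 nt then differed by 4.10 and -4.10, which is a single contrast and not 2 checks. The log2 ratio of distinct fragments was 0.10 and, not thinned, 0.94. The log2 read ratio ran from 1.83 without untreated 1 to 2.37 without untreated 2. With each distinct fragment counted once it becomes the ratio of distinct fragments not thinned, 0.94, and is no separate check. No paired analysis was possible because the numbers of the tables do not match those of the labels in both groups. The 20 nt minimum, exact matching and single strand removed no read and tested nothing. Counting each fragment once was not run for single fragments, a choice made after its values were seen, since it fixes their shares. Except for counting fragments once, the cause of the changes below was not tested.

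With each distinct fragment counted once, differences (CSE minus untreated, percentage points) were -3.85 for 5' end 22, -3.17 for 3' end 95, 2.23 and -4.64 for coverage of positions 48 and 80, -0.522, 0.360 and 0.00658 for 5' ends 55 and 35 and 3' end 61, all reversed, and 0.919 and -0.627 for reads up to 30 nt and position 16, past the threshold no more. At 22 and 95, 1 end can form at most 43 fragments (42 and 43 were seen at either end in CSE). CSE libraries list more reads, so such ends lose share in them, and the reversals there are no test of those results. In draws of 984 reads per library, added after this was seen, the differences were -3.470e-05 at 22, -0.212 at 95, -0.645 at 48 and -2.33 at 80. The reversal at 48 was thus gone. At 95 it stayed, with 8.75% and 8.49% in CSE 3 and CSE 4 and 8.90% and 8.77% in untreated 1 and 2. Unequal read numbers alone do not account for it. CSE 3 and CSE 4 held more distinct fragments that end at 95 (36.0 and 35.8 expected, against 34 and 34.8 in untreated 1 and 2). Their totals of distinct fragments were larger too (411 and 422 against 382 and 397), which lowers the share. With at most 43 fragments per end, this reversal is no test of the share of reads at 95 either. Reads with both ends observed gave -1.63 and -2.45 at positions 48 and 80 and 0.0561 at 3' end 87. Without 53 to 54 nt reads, 5' end 22 turned to -0.0145, 5' end 35 to 0.147 and 3' end 88 to 0.0687, and reads up to 30 nt gave 1.24. Pooling ends within 2 nt turned 5' end 22 to -1.10.

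The scans called 3 5' ends higher and 5 lower, 4 and 6 3' ends, 2 and 8 fragments, and 1 and 4 lengths. Once-counted fragments gave 0 and 1 5' ends, 0 and 0 3' ends, and 0 and 0 lengths, again with unequal read numbers. Both ends observed gave 3 and 3 5' ends, 8 and 5 3' ends, 2 and 8 fragments, and 3 and 4 lengths. Without 53 to 54 nt reads there were 1 and 1 5' ends, 4 and 5 3' ends, and 2 and 3 fragments. edgeR with the reads listed gave 0 and 0 5' ends, 1 and 1 3' ends, 0 and 1 fragments, and 1 and 2 lengths. With TMM factors it gave 0 and 0, 0 and 0, 2 and 1, and 1 and 4. DESeq2 gave 1 and 1, 1 and 1, 0 and 0, and 0 and 0.

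Leaving out 1 library at a time, calls ranged from 0 to 4 higher and 1 to 6 lower for 5' ends, 1 to 8 and 2 to 8 for 3' ends, 1 to 4 and 1 to 5 for fragments, and 0 to 3 and 2 to 3 for lengths. Reads up to 30 nt ranged from 0.767 to 3.02, 5' end 22 from -0.685 to 1.79, position 16 from -0.807 to -0.0290, position 48 from -6.72 to -2.71 (-4.72 with all libraries) and position 80 from -2.58 to 3.84. Uncalled features that turned were 5' ends 55 (-0.397 to 1.52), 58 (-0.643 to 0.178) and 26 (-0.473 to 1.63), 3' ends 87 (-0.971 to 0.0304) and 88 (-1.09 to 0.172), and fragments 22-91 (-0.452 to 1.83), 22-87 (-0.310 to 0.0756), 22-50 (-0.0580 to 0.703) and 22-88 (-0.528 to 0.0602). All other single features kept their direction without any 1 library. Calls rest on the adjusted p and were often lost where the direction held, as given in the results. Under the settings above, the threshold was set on the unadjusted Fisher's exact p, which is not the rule for a call. Of the values of single features that kept their direction there, 107 kept their side of that threshold, 18 lost it and 1 passed it. A further 6 values turned. The 107 include those without reads in the second copy. That setting kept 12557 of 12591 reads and could change little, so the 107 overstate how stable the features were. The floor of 3 reads was 0.305% in untreated 1, which limits rare fragments most.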

Other observations

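The tests on the join, on library depth and on 53 to 54 nt reads and the splits for the scan of lengths were chosen after the results were seen, unlike the splits for the other scans and the test of copied molecules.

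Few reads began before position 22: 1.91% ± 0.390 (n = 2) of CSE and 2.65% ± 0.570 of untreated reads. Among the 3145 reads that begin there, 470 had the longest listed length of 70 nt and 74 had 69 nt. Reads of 70 nt formed 20.3% (Wilson interval 18.1 to 22.7) of the reads from position 22 in CSE 3, 11.2% (9.67 to 13.0) in CSE 4, 16.1% (12.1 to 21.2) in untreated 1 and 10.2% (7.40 to 13.9) in untreated 2. The replicates of CSE thus differed by more than counting error in how far these reads extend. Untreated 1 likewise lay above untreated 2, with overlapping intervals. Of all reads, those of 70 nt formed 6.08% and 3.48% in CSE 3 and CSE 4 and 5.28% and 3.36% in untreated 1 and 2. The difference between replicates was therefore not particular to CSE, and its cause was not tested.

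The CSE libraries listed 4.22 times more reads. Copying of fewer molecules would lower the number of distinct fragments in draws of equal read number. The CSE over untreated ratio was 1.07, with both CSE libraries above both untreated ones. The excess lay mainly in fragments of 31 to 50 nt (250 and 260 expected in CSE 3 and CSE 4, 203 and 221 in untreated 1 and 2). Over 50 nt, CSE libraries held fewer (118 and 112 against 138 and 139). The ratio thus also follows the shift in length, and the test cannot decide on copying. Larger CSE libraries and more RNA of the region in treated cells cannot be told apart, because no library totals were used here to set against the ratio of 4.22. An effect of smoke remains an open hypothesis.

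Reads of 53 to 54 nt were 2.12 times more frequent in untreated libraries. A gel selection that changes smoothly with length would also shift the neighbouring lengths. The ratio for 51 to 52 nt reads was 1.12 (1.12 on pooled reads, interval 0.934 to 1.34), below the bound of 1.5 set for that explanation, which argues against it on the shorter side. Reads of 55 to 56 nt did shift, with a ratio of 1.51 (1.48 on pooled reads, interval 1.21 to 1.82), an interval that spans the bound, as did that of 57 to 61 nt reads (ratio 1.31, pooled interval 1.08 to 1.52). Reads of 62 to 69 nt had a ratio of 1.03 (1.05 on pooled reads, interval 0.892 to 1.23, and 1.26 for the higher untreated over the lower CSE library), which argues against a selection that shifts all longer reads. Reads of 70 nt, which may be longer than listed, had a ratio of 0.905. A selection confined to about 53 to 61 nt stays open. A single cut site or fragment is argued against because no 5' or 3' end held more than 15.6% of the excess, while both untreated libraries lay above both CSE libraries at 12 of 19 5' ends and 12 of 17 3' ends with at least 10 such reads (17 and 16 by group means). A change in the RNAs of treated cells was not tested.

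A few reads crossed the join of the doubled region: 0.178% ± 0.0181 (n = 2) of CSE and 0.207% ± 0.00494 of untreated reads, with Wilson intervals that overlap. Among reads with at most 4 bases past the join, the length of the random adaptor stretch, 38.1% had 2 or more (exact interval 18.1 to 61.6). Chance matches would give 24.7%, but so wide an interval cannot decide whether untemplated adaptor bases account for them. The test also left out how many reads crossed: 2513 reads stopped at position 95 and 13 ended 1 base past it. Chance would match that base in 25% of reads that kept adaptor bases, and how many kept them is not known. Overhangs longer than 4 bases were found in 2 of 23 reads, of 7 and 10 nt, where chance would give 0.0898 reads (one-sided exact binomial p = 0.00366). What produced those 2 reads, 1 in each group, was not tested.

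The 4 libraries can be split into groups of 2 in 3 ways, too few for a share under 0.05. In each of the 4 scans, only 1 split, the real one, reached the real count. It called 8 5' ends against 3 in the highest other split, 10 3' ends against 5, 10 fragments against 4, and 5 lengths against 3. For 3' ends, fragments and lengths, the highest other split set CSE 3 and untreated 1 against CSE 4 and untreated 2. For 5' ends it set CSE 3 and untreated 2 against CSE 4 and untreated 1.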
